A study of Homo sapiens with 6 samples.

How the data were processed

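Gene expression was measured in 6 xenograft tumours of NCI-H69, an established human small cell lung cancer line, grown in SCID mice, which lack working T and B cells. In 3 tumours the RNA was taken 4 h after PDT, read here as photodynamic therapy because the labels speak of sensitising; the other 3 tumours were untreated and collected in parallel. Per the labels' protocols, total RNA was extracted with Trizol from frozen, pulverised tissue, and biotin-labelled cRNA was hybridised to human Affymetrix arrays. The labels call the tumours of a group biological replicates, so the limma p-values of probe sets and genes measure the spread between these tumours. The p-values of the list test at a preset correlation, described below, rest largely on the spread over genes instead.

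The values analysed are the authors' deposited linear ratios, 1 per probe set and array. GCOS and RMA are named, without versions, per the submitters' processing notes, and the step that made ratios of the signals is not given in the sources used here. The values show it: the deposited ratio of each probe set has a median over the 6 arrays between 0.99 and 1.005, and each array has a median ratio of exactly 1. A probe set's value therefore says how it compares with its own middle level over the 6 arrays, and nothing about how strongly the gene was expressed. Signal over background cannot be read from such values, so detection is unknown for every gene, and the number of arrays limits the precision. Of 22277 probe sets listed, 62 array controls had no value, which rules out a 3'/5' check of RNA quality, and 22215 were analysed. The platform annotation gives 1 gene symbol for 19064 of these, several for 1043 and none used here for 2108; 12 single-symbol probe sets had an Entrez identifier that the reference table lacks and kept the annotation's symbol. Probe sets with several symbols name no gene in the text. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. All 6 columns of the deposited table were used.

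The ratios were transformed to log2 with no pseudocount and no further scaling. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, all 6 arrays), with Benjamini-Hochberg adjustment and a threshold of 0.05. For genes, the log2 values of all single-symbol probe sets of a gene were averaged, which gave 11963 genes, 4310 of them with over 1 probe set. The design written before the data were examined had taken the probe set with the highest mean; ratios hold no level to rank by, so the average, listed beforehand as another setting, became the value reported and the highest-mean probe set the alternative. Where probe sets of a gene disagree, the average hides it: the treated minus untreated differences of 2 probe sets of a gene correlated across genes at r = 0.28 in pair 1, 0.55 in pair 2 and 0.38 in pair 3 (genes are not independent replicates).

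Lists of genes for stress responses, metabolism, cell cycle, neuroendocrine identity and 7 host cell types were fixed before the data were examined: 27 lists with 842 members, 729 of them measured. Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 27 lists. Camera with an estimated correlation and fry, whose directional test asks whether the members move one way on balance, were alternatives. At the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes them from the arrays, which are few here. Member counts are also given adjusted over the list alone. The rule for named genes took 12 genes per direction from those past the threshold or, since none passed, the 5 genes with the smallest p in each direction, then up to 4 members of each list by smallest p, and 13 genes fixed in advance, of which 11 were measured. Genes named outside that rule are marked as chosen after their values were seen. Y-linked genes and XIST are not reported.

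Treated and untreated tumours share replicate numbers, and the series describes 3 pairs with parallel collection. Deviations of same-numbered arrays from their group means correlated across probe sets at r = 0.71 for pair 1, 0.50 for pair 2 and 0.48 for pair 3, so the numbers were taken to pair the samples. For numbers 2 and 3 these values do not single out the same-numbered arrays: treated 2 correlated with untreated 3 at r = 0.49 and treated 3 with untreated 2 at r = 0.51. Without pair 1, the difference between treated 2 and treated 3 correlated with that between untreated 2 and untreated 3 at r = -0.022, so for these the pairing rests on the series' description. The reported fit leaves the pairing out, as set before the data were examined, and the fit with the replicate number as a block is an alternative. Other settings fixed beforehand were quantile normalization, median centring, eBayes with trend and robust, leaving out each array, a 2-fold minimum, an adjusted p of 0.1, leaving out probe sets that can match several transcripts, and the list tests named above. Fits without each replicate pair were added after the data were seen. The planned removal of the 40% dimmest probe sets was not run, since ratios carry no brightness.

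The fits were tested on simulated data: log2 values were drawn with the residual spread of each of 22215 probe sets, and 200 probe sets were changed by known folds. With all 6 arrays, 38% of 2-fold, 66% of 4-fold, 86% of 8-fold and 94% of 16-fold changes were recovered. With the replicate block these shares were 22%, 70%, 86% and 98%, and without pair 1 they were 12%, 70%, 76% and 94%. The simulation drew each probe set independently, which the real arrays are not. It also gave all treated arrays the same fold, so the shares do not apply to changes whose size varies between tumours. BAG3, for example, was higher by log2 2.35, 5.58 and 3.60 in the 3 pairs. At 14.3-fold over all arrays it had a limma adjusted p = 0.99958 over all genes. For the list test, 27 lists of 26 genes were simulated over 11963 genes, and camera called all 5 lists shifted by 0.5 log2 and 0 of the others with either correlation setting. Genes were drawn independently here too. This run therefore does not show how either setting behaves for correlated members, such as heat shock genes (correlation estimated at 0.47). The shift was also larger than the median of any list called in the real data, the largest being 0.37. Figures were drawn with matplotlib 3.10.9.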

Results

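The study asked how xenografts of the neuroendocrine lung cancer line NCI-H69 change their gene expression early after PDT. It compared 3 treated tumours taken 4 h after PDT with 3 untreated tumours taken in parallel, with 1 human array per tumour. Values are log2 ratios to each probe set's median over the 6 arrays, so they compare tumours and hold no expression level. All errors are the SE of the log2 difference with n = 3 tumours per group, or n = 2 in fits without pair 1, unless an SD is named.

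Treated tumours had higher signals of 2 families of rapid stress genes: immediate early transcription factor genes such as FOS and ATF3, and heat shock genes such as BAG3 and HSPB1. Genes of inflammation, hypoxia and red blood cells were also higher as lists, and genes of cell division, cholesterol synthesis, respiration and ribosomes were lower as lists, by smaller amounts. No list call held with an estimated correlation between genes (0 of 27, lowest adjusted p = 0.11 with an estimated correlation). Calls were lost also for lists whose estimate lay below the preset, so correlation between members is not the sole reason. The estimated setting also counts degrees of freedom by arrays, where the preset counts them by genes. The changes named above are shifts of gene lists and of members judged within their list. No single gene passed a test over all genes in the main fit, which takes all 6 arrays.

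Over all 22215 probe sets, limma called 0 (lowest adjusted p = 0.99985), with 769 at an unadjusted p under 0.05, 445 higher and 324 lower, where chance alone would give 1110.8. Over the 11963 genes it also called 0, with 396 at an unadjusted p under 0.05. With the replicate number as a block the calls were again 0 and 0. At an unadjusted p under 0.05 there were then 1424 probe sets and 829 genes, where chance alone would give 1110.8 and 598.15. The main fit counts offsets between pairs as spread within the groups, which the block removes. The 3 treated values lay wholly above the 3 untreated ones for 1223 probe sets and wholly below for 1072, together 10.3%, and chance gives 10%. By pair, 15.5% of probe sets were higher in all 3 pairs and 14.1% lower, where chance gives 12.5% each; probe sets are not independent, so these excesses were not tested. A probe set of DUSP1, a phosphatase gene that switches off MAP kinases, passed when eBayes was run with trend and robust (log2 1.52, SE 0.16, adjusted p = 0.0053). Averaged over its 2 probe sets, DUSP1 had log2 0.74 (SE 0.18) in the main fit, so the other probe set lay far lower. The 5 genes with the smallest p among those higher were FOS, IER3, ATF3, CRYAB and HBB, and among those lower CCDC106 (log2 -0.62, SE 0.10), TOMM40, a pore subunit for mitochondrial protein import (-0.60, SE 0.13), NLK, a kinase (-0.48, SE 0.10), UTRN, which encodes utrophin (-1.36, SE 0.29), and APP, the amyloid precursor protein gene (-0.59, SE 0.13). None of these 10 passed over all genes (adjusted p = 0.99958 each).

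The list of immediate early and AP-1 genes, which answer growth factors and stress within minutes to hours, rose after PDT (camera adjusted p = 2.8e-11, 43 members, median log2 0.32). Its adjusted p = 0.11 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 12 passed, all higher. FOS, a subunit of the AP-1 transcription factor, was 4.75-fold higher (log2 2.25, SE 0.31, adjusted p = 0.0071 over the list alone), and ATF3, a stress-induced transcription factor gene, was 5.02-fold higher (log2 2.33, SE 0.35). By pair, FOS was higher by log2 2.61, 1.37 and 2.77 and ATF3 by 1.60, 3.33 and 2.05. IER3 was 2.21-fold and MAFF 2.08-fold higher. Further AP-1 and growth response genes fixed in advance also passed within the list: EGR1 at 2.22-fold (log2 1.15, SE 0.21) and JUN at 1.78-fold (log2 0.84, SE 0.17). The other 31 members did not pass. The list's median difference was 0.33 in pair 1, 0.25 in pair 2 and 0.23 in pair 3. Leaving out any single array kept this call.

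Heat shock and chaperone genes, which refold damaged proteins, rose as a list (camera adjusted p = 3.8e-09, 26 members, median log2 0.37, mean 0.90), with adjusted p = 0.36 with an estimated correlation (estimated at 0.47). Adjusted over the list alone 6 members passed, all higher, and 0 passed over all genes; without pair 1, 14 passed within the list. BAG3, a co-chaperone gene, was 14.3-fold higher (log2 3.84, SE 0.79, adjusted p = 0.024 over the list alone), DNAJB1, which encodes an HSP40 protein, 4.92-fold (log2 2.30, SE 0.50), HSPB1, which encodes HSP27, 3.38-fold (log2 1.76, SE 0.39), and the small heat shock gene CRYAB 2.47-fold (log2 1.31, SE 0.20). The other members to pass, singled out after their values were seen, were the inducible HSP70 gene HSPA6 at 21.6-fold (log2 4.43, SE 1.09) and the collagen chaperone gene SERPINH1 at 9.51-fold (log2 3.25, SE 0.83). The size differed between pairs: BAG3 was higher by log2 2.35 in pair 1, 5.58 in pair 2 and 3.60 in pair 3, HSPB1 by 0.63, 2.82 and 1.82, DNAJB1 by 1.5, 3.68 and 1.72, and the list's median by 0.12, 0.88 and 0.25. HSPA6 was higher by log2 3.08 in pair 1, 6.65 in pair 2 and 3.58 in pair 3, and by 5.11 in the fit without pair 1. The fixed gene HSPA1A had no single-symbol probe set.

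**Figure D1:**
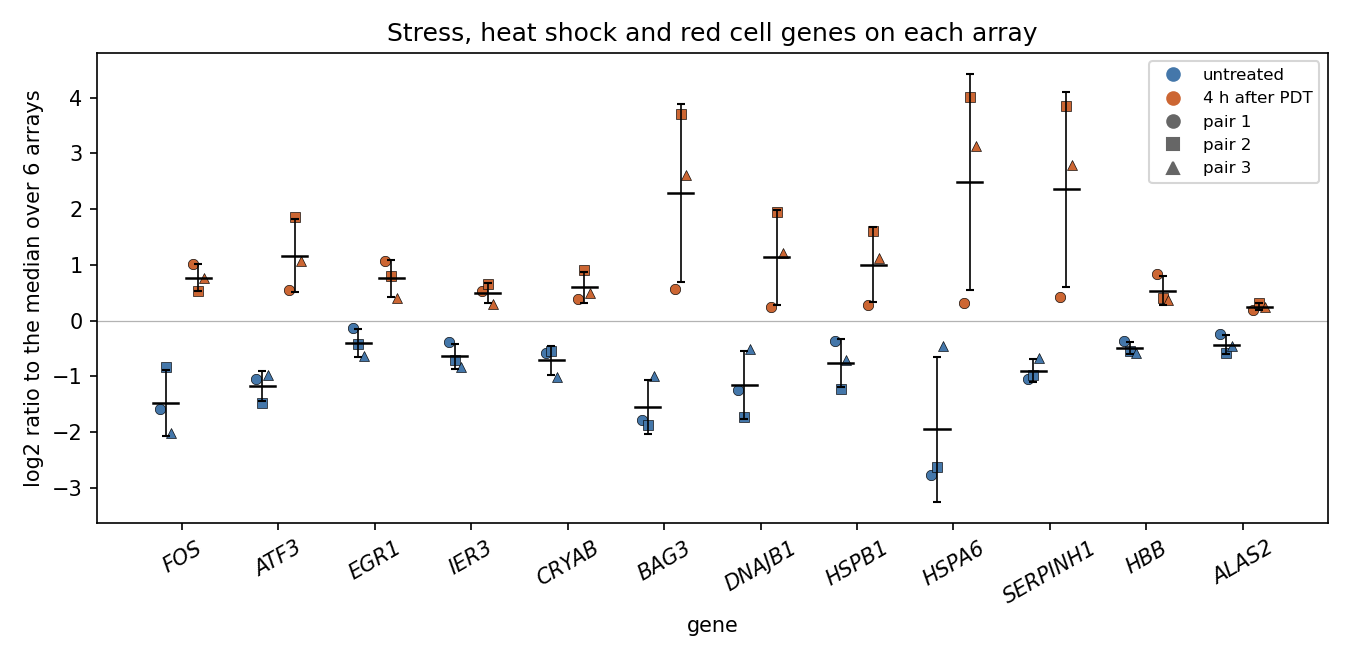
Log2 ratios of 12 genes on each array (vertical axis), untreated tumours in blue and tumours 4 h after PDT in orange, with marker shapes for the replicate pairs and bars for the mean and SD of 3 tumours. In each of these genes the 3 treated values lie above the 3 untreated ones. The treated value of pair 1 is the lowest of the 3 treated values for ATF3, ALAS2, CRYAB, BAG3, DNAJB1, HSPB1, HSPA6 and SERPINH1. For FOS, EGR1, IER3 and HBB it is not the lowest.

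Genes induced by NF-kB and inflammatory cytokines rose as a list (camera adjusted p = 3.0e-05, 35 members, median log2 0.16; adjusted p = 0.25 with an estimated correlation). IER3, which is on this list too, was the 1 member to pass adjusted over the list alone, against 5 members without pair 1. TNFAIP3, a feedback inhibitor of NF-kB, was 4.30-fold higher (log2 2.10, SE 0.54; 0.38 in pair 1, 2.80 in pair 2, 3.13 in pair 3) and the chemokine genes CCL20 (log2 0.45, SE 0.11) and CCL5 (log2 0.29, SE 0.11) were higher in every pair without passing. The interferon response list rose (camera adjusted p = 4.4e-04, 36 members, median log2 0.099; adjusted p = 0.31 with an estimated correlation), with 0 members passing within the list; IFIT2 had the smallest p (log2 0.55, SE 0.12), followed by IFITM1 (log2 0.35, SE 0.13). Its call was lost without treated tumour 1 (adjusted p = 0.078).

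Hypoxia and glycolysis genes rose as a list (camera adjusted p = 0.0051, 40 members, median log2 0.20; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone 0 members passed, while 7 passed with the replicate block and 6 without pair 1. The 4 members with the smallest p were the collagen hydroxylase genes P4HA1 (log2 0.60, SE 0.12) and P4HA2 (log2 1.02, SE 0.25), MXI1 (log2 0.63, SE 0.18) and, in the other direction, LOX, a collagen cross-linking enzyme gene (log2 -0.54, SE 0.12). VEGFA, the vascular growth factor gene, had log2 0.77 (SE 0.40), with 0.083 in pair 1, 1.29 in pair 2 and 0.93 in pair 3. The call was lost without treated tumour 2 (adjusted p = 0.053). Genes of ATF4 and the amino acid response rose as a list (camera adjusted p = 0.016, 33 members, median log2 0.16; adjusted p = 0.49 with an estimated correlation), with 0 members passing within the list. Here the median difference was 0.051 in pair 1, 0.46 in pair 2 and -0.0067 in pair 3, and the call was lost without treated tumour 2 (adjusted p = 0.51) or untreated tumour 2 (adjusted p = 0.33). HERPUD1 (log2 0.85, SE 0.26), DDIT4 (log2 0.70, SE 0.30) and DDIT3, which encodes CHOP (log2 0.81, SE 0.43), did not pass.

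Lists of cell division genes fell by small amounts. The G2/M cell cycle list fell (camera adjusted p = 2.3e-05, 40 members, median log2 -0.16; adjusted p = 0.11 with an estimated correlation), and so did the list of G1/S and DNA replication genes (camera adjusted p = 0.0036, 40 members, median log2 -0.16; adjusted p = 0.17 with an estimated correlation). In both lists 0 members passed within the list: the mitotic kinesin gene KIF2C had log2 -0.44 (SE 0.14), the cyclin gene CCNB1 -0.29 (SE 0.14), the thymidylate synthase gene TYMS -0.32 (SE 0.11) and the chromatin assembly gene CHAF1A -0.51 (SE 0.18). The G1/S call was lost without treated tumour 1 (adjusted p = 0.13).

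Cholesterol and lipid synthesis genes fell as a list (camera adjusted p = 1.2e-04, 25 members, median log2 -0.25; adjusted p = 0.31 with an estimated correlation). HMGCS1, an early enzyme gene of the pathway, had log2 -0.41 (SE 0.13), and ACLY, which supplies acetyl-CoA, -0.31 (SE 0.11); 0 members passed within the list. The median difference was -0.35 in pair 1 against -0.091 and -0.16 in the other pairs, and the call was lost without treated tumour 1 (adjusted p = 0.068) and without pair 1 (adjusted p = 0.066), the latter fit added after the data were seen. The oxidative phosphorylation list fell (camera adjusted p = 2.2e-04, 52 members, median log2 -0.10; adjusted p = 0.43 with an estimated correlation), although its median difference in pair 1 was 0.086. The ribosomal protein list fell (camera adjusted p = 4.4e-04, 51 members, median log2 -0.068; adjusted p = 0.43 with an estimated correlation). In both, 0 members passed within the list; NDUFB7, a complex I gene, had log2 -0.51 (SE 0.19) and RPS28 -0.31 (SE 0.16). The oxidative phosphorylation call was lost without treated tumour 2 (adjusted p = 0.085) and without pair 2 (0.14, or 0.18 with the replicate block). The ribosomal call was lost without untreated tumour 3 (adjusted p = 0.13) and without pair 3 (0.20, or 0.34 with the replicate block).

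**Figure D2:**
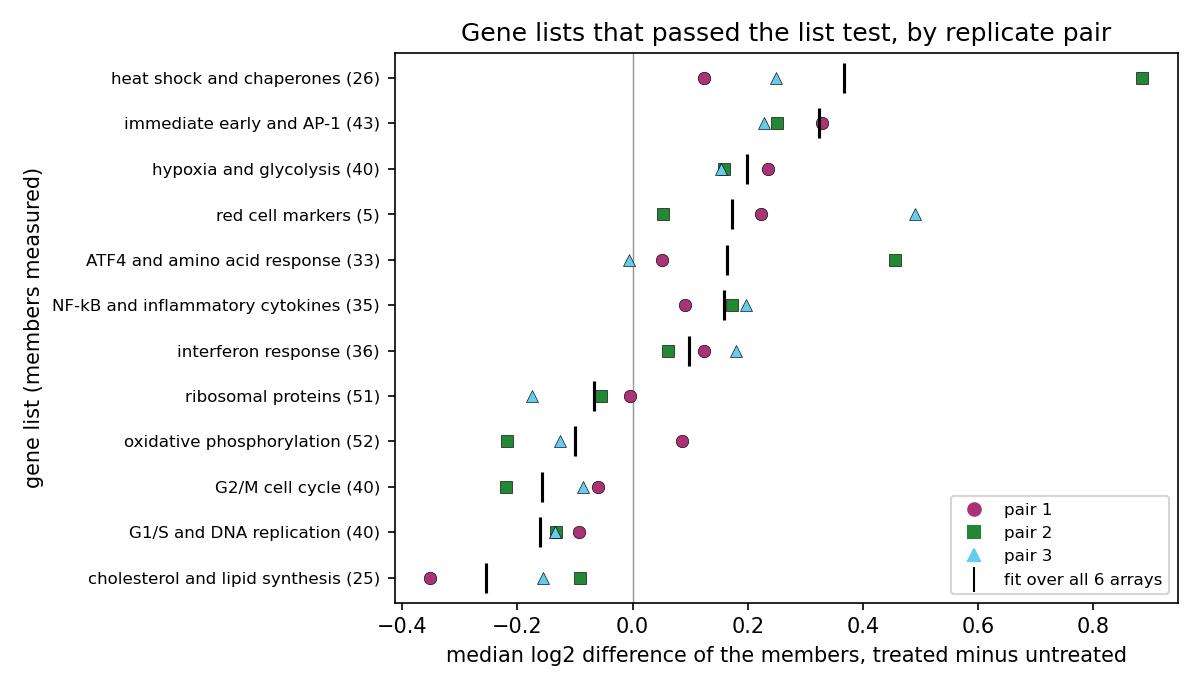
Median treated minus untreated log2 difference of the members (horizontal axis) for each of the 12 gene lists that passed the list test, with 1 marker per replicate pair and a bar for the fit over all 6 arrays. Heat shock genes reach 0.88 in pair 2 against 0.12 in pair 1, and the oxidative phosphorylation list has a positive median in pair 1 (0.086) and negative ones in the other pairs.

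Several responses often linked to oxidative injury did not pass as lists over all 6 arrays. NRF2 and antioxidant defence genes had a median log2 of 0.012 over 38 members (camera adjusted p = 0.68), and HMOX1, the inducible haem oxygenase gene, was 1.87-fold higher (log2 0.90, SE 0.33) without passing; it was higher by 0.086 in pair 1, 1.51 in pair 2 and 1.11 in pair 3. Genes of the unfolded protein response in the ER had a median of 0.042 over 27 members (adjusted p = 0.33), with HSPA5, which encodes BiP, at log2 0.56 (SE 0.33). The 9 metallothionein list members had a median of 0.16 (adjusted p = 0.071), which passed with the replicate block (adjusted p = 0.046), and adjusted p = 0.75 with an estimated correlation and the block. Its median difference was -0.21 in pair 1, 0.12 in pair 2 and 0.64 in pair 3. The p53 target list had a median of -0.046 over 22 members (adjusted p = 0.50), and CDKN1A, the p21 gene, had log2 0.30 with an SE of 1.12 (0.38 in pair 1, 0.085 in pair 2 and 0.44 in pair 3). That SE includes an offset of pair 1, where CDKN1A was high in both tumours (log2 ratio 2.59 treated, 2.21 untreated). Apoptosis machinery genes had a median of -0.043 over 32 members (adjusted p = 0.29), with BCL2L1, an anti-apoptotic gene, at log2 -0.88 (SE 0.28), or -0.49 without pair 1, where it was -1.67. Replication-dependent histone genes had a median of -0.26 over 16 members (adjusted p = 0.33), with 0.44 in pair 1 against -0.63 and -0.18 in the others. Haem and porphyrin metabolism (median -0.052, 19 members, adjusted p = 0.50), the proteasome (median -0.0080, 33 members, adjusted p = 0.50) and neuroendocrine genes of small cell lung cancer (median -0.13, 28 members, adjusted p = 0.53) did not pass either; the last list passed, lower, without pair 3 with the replicate block (adjusted p = 0.023). Within it, CHGA had log2 -0.32 (SE 0.44) and ENO2 0.53 (SE 0.15). MYC had log2 0.36 (SE 0.22). Some of these lists passed after other changes of the input: the unfolded protein response without untreated tumour 1 (adjusted p = 0.0070), histones with quantile normalization (0.0084) or without treated tumour 1 (1.2e-04), and metallothioneins with quantile normalization (0.0045) or without treated tumour 1 (0.0018), untreated tumour 1 (0.036) or untreated tumour 2 (0.021).

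Markers of host cells, which a human array can read in mouse RNA only where probes match it, were tested the same way. Red cell markers rose as a list (camera adjusted p = 2.5e-04, 5 members, median log2 0.17; adjusted p = 0.29 with an estimated correlation), and adjusted over the list alone 2 passed: HBB, the beta globin gene, at 2.04-fold (log2 1.03, SE 0.16, adjusted p = 0.0032) and ALAS2, the first enzyme gene of haem synthesis in red cells, at 1.60-fold (log2 0.68, SE 0.13). AHSP (log2 0.17, SE 0.12) and HBD (0.13, SE 0.12) did not pass, nor did SLC4A1 (-0.064, SE 0.23), the remaining member, named after its value was seen. This list moved in the same direction as the stress lists, and its call held without any single array but was lost without pair 3 with the replicate block (adjusted p = 0.071). The other host lists did not pass: endothelium (median 0.036, adjusted p = 0.53), fibroblast and smooth muscle (median 0.050 and mean -0.0089, adjusted p = 0.91), macrophage and neutrophil (median 0.0087, adjusted p = 0.45), lymphocyte (median -0.020, although camera's direction was upward, adjusted p = 0.82), skeletal muscle (median 0.029, adjusted p = 0.85) and skin keratinocyte (median 0.051, adjusted p = 0.31), which passed without untreated tumour 3 (adjusted p = 0.013) and without pair 3 (0.031).

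The tumours of pair 1, treated and untreated, stood apart from the other 4. Treated tumour 1 and untreated tumour 1 had 2295 and 1243 probe sets over 2-fold from their median, and the other arrays 78 to 170. Across probe sets, treated 1 correlated with untreated 1 at r = 0.68 and with the other treated tumours at -0.26 and -0.29. Ratios to a median over the same arrays tend to push such correlations below 0, so a negative r is not by itself an opposite profile. Treated 2 and untreated 2 correlated at -0.15, and treated 3 and untreated 2 at -0.10. The treated minus untreated differences correlated across probe sets at r = 0.13 between pairs 1 and 2, 0.055 between pairs 1 and 3 and 0.29 between pairs 2 and 3 (probe sets are not independent replicates). In pair 1, 1043 probe sets were over 2-fold lower and 136 over 2-fold higher after PDT, against 147 lower and 192 higher in pair 2 and 175 lower and 195 higher in pair 3.

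**Figure D3:**
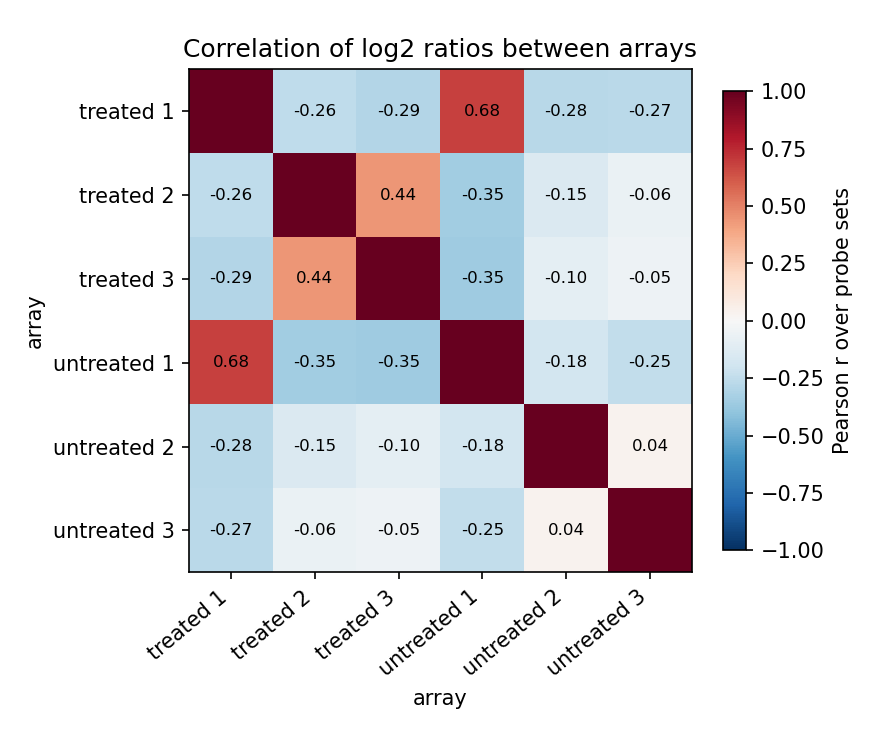
Pearson correlation of log2 ratios over 22215 probe sets between each pair of the 6 arrays (both axes), as colour and number. Treated 1 and untreated 1 correlate at 0.68, treated 2 and treated 3 at 0.44, and pair 1 has negative correlations with all other arrays. Ratios to a median over the same arrays tend to push correlations below 0, and treated 2 with untreated 2 is also negative (-0.15).

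Without pair 1, a fit added after the data were seen, limma called 18 probe sets from 2 tumours per group, 16 higher and 2 lower, all with adjusted p = 0.0499, so each sits at the threshold. Of these, 12 have a single gene symbol and name 10 genes, 5 list both alpha globin genes, which they cannot tell apart, and 1 is not named here. The genes, read from the fit without pair 1, included BAG3 (log2 4.59, SE 0.41), SERPINH1 (4.14, SE 0.33), TNFAIP3 on both of its probe sets (3.06, SE 0.30, and 2.86, SE 0.28), CLU, which encodes the extracellular chaperone clusterin (2.33, SE 0.24), HSPB1 (2.32, SE 0.24), FAM149A, GADD45B (1.72, SE 0.17), DUSP1 (1.60, SE 0.14) and RNF130 among those higher, and a probe set of DST, the dystonin gene (-1.61, SE 0.16), among those lower. These are values of single probe sets. Averaged over all its probe sets without pair 1, GADD45B had log2 0.79 (4 probe sets) and DUSP1 0.85 (2 probe sets). In pair 1 itself 16 of the 18 called probe sets differed in the same direction. With the replicate block as well, 87 probe sets passed, 66 higher and 21 lower, and 10 genes passed: BAG3, SERPINH1, TNFAIP3, FAM149A, CRYAB, RGS2, PARP12, NKX2-2 and PPP1R15A were higher and MARCHF1 was lower. That fit with the block leaves 1 residual degree of freedom, so its p-values lean on the variance shared across probe sets or genes. It was not simulated, and for numbers 2 and 3 the values themselves showed no pairing (r = -0.022). Averaged over probe sets and without the block, 0 genes passed (lowest adjusted p = 0.12). In pair 1, 3 of the 10 genes had the opposite sign: PPP1R15A, a phosphatase subunit gene of the stress response (-1.33 in pair 1, 2.05 in pair 2 and 1.69 in pair 3), MARCHF1 (0.55, -1.89 and -2.03) and NKX2-2 (-0.096, 1.93 and 2.04). Leaving out pair 2 or pair 3 in the same way gave 0 calls. Of the gene lists, 14 passed without pair 1, 11 of them among the 12 that passed over all arrays, and 0 with an estimated correlation. The 3 lists gained were the unfolded protein response, higher (adjusted p = 0.026, and adjusted p = 0.38 with an estimated correlation), metallothioneins, higher (3.7e-04, and 0.48), and replication-dependent histones, lower (6.8e-06, and 0.34).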

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

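Fits without a replicate pair, and the replicate block together with an estimated correlation or fry, were chosen after seeing the data. The counts of 0 probe sets and 0 genes held under the replicate block (0 and 0), quantile normalization, median centring, and without any single array (0 to 0). The exceptions were 1 probe set with trend and robust, which rests on mean ratios that hold no level; 18 probe sets without replicate pair 1; and 87 probe sets and 10 genes without replicate pair 1 with the replicate block. The 12 lists became 13 with the replicate block and 9 to 14 without 1 array. With camera's estimated correlation the count was 0, also 0 with the block. For G2/M, G1/S and hypoxia genes the estimates (-0.0024, -0.018 and 0.0026) lay below the preset of 0.01. Correlation between members therefore does not account for losing these calls. The degrees of freedom, counted by genes at the preset and by arrays with an estimate, changed for every list. The list calls thus depend on counting genes. By fry 2 lists moved one way (immediate early and G2/M genes) and 3 changed in either direction (immediate early, NF-kB and red cell genes). Heat shock genes passed no fry test (fry adjusted p = 0.29 one way, 0.21 in either direction, 0.39 one way with the block). By fry with the replicate block 3 lists moved one way: immediate early, hypoxia and G1/S genes (adjusted p = 0.045, 0.045 and 0.010), while G2/M did not pass (0.18). With camera at the preset correlation, the replicate block changed only the metallothionein call. Without replicate pair 2, camera's direction for the ATF4 list turned while its median stayed positive (0.0052). Among named genes that passed in no setting, signs turned for CDKN1A (-0.66 to 1.22 without 1 array), KRT5 (-0.0023 to 0.38), CSF1R (-0.0014 to 0.18, and -0.022 without pair 1), CHGA (-0.71 to 0.16, and 0.032 without pair 1), MB (-0.057 to 0.98, and -0.010 without pair 3), KRT1 (-0.20 to 0.029, and 0.026 without pair 3), PLK3 without pair 2 (-0.030), MT1F (-0.017) and MT1M (-0.020) without pair 3, and, with the highest-mean probe set, BUB1 (0.13), PSME3 (0.097) and ACTA2 (0.037). The causes were not tested. The planned removal of dim probe sets was not run, and signal over background, which would limit dim genes, cannot be read from ratios.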

Other observations

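Apart from the correlation between 2 probe sets of a gene, the probe sets lost in pair 1 and the genes shifted on 2 probe sets, the tests here were chosen only after the result was seen. Pair 1 differed from the other tumours in named genes, compared here after the values were seen. Of 22215 probe sets, limma called 3519 between the 2 tumours of pair 1 and the other 4 (15.8%), 1904 higher and 1615 lower. NELL2, a secreted neural protein gene, was 102-fold higher in pair 1, CHRDL1, a BMP antagonist gene, 75.8-fold and SOCS2, a suppressor of cytokine signalling, 43.9-fold, while the sodium channel gene SCN3A was 99.7-fold lower and PKIG, a protein kinase A inhibitor gene, 16.7-fold lower. Among 28 neuroendocrine genes, 6 differed at least 2-fold: the secretory granule genes CHGB (log2 2.67), SCG3 (2.36) and SCG2 (1.49) and the peptide gene GRP (2.19) were higher in pair 1, and SOX2 (-1.28) and STMN2 (-1.08) lower.

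What sets pair 1 apart is reproducible between probes: the offsets of 2 probe sets of the same gene correlated at r = 0.56 across 4310 genes, which argues against noise of single probe sets. A small share of host RNA added in pair 1 would raise signals and lower none by 4-fold, yet 195 probe sets were at least 4-fold lower, against 279 at least 4-fold higher. A large share could lower tumour signals that far after scaling. More host RNA in the other pairs was not considered, so these counts do not exclude a difference in host share. In 41 genes 2 probe sets shifted at least 4-fold the same way, and in 0 opposite ways. A tumour cell source other than that of pairs 2 and 3 could account for this, but a shared batch, passage or day of pair 1 could too, and with no profile of the line to compare with these cannot be told apart. No biological explanation was tested.

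The second pattern is that 0 probe sets passed over all 3 pairs, for which the offset shared by both arrays of pair 1 is not the whole reason: the replicate block removes it, and 0 probe sets passed with it. With the block, 87 probe sets passed without pair 1 and 0 without pair 2 or 3, counts known beforehand that do not test whether the response of pair 1 differed. Signal lost from single probe sets on the treated array of pair 1 may contribute: where 1 probe set of a gene was at least 2-fold lower there, the gene's other probe sets had a median of -0.19 (95% bootstrap interval -0.23 to -0.15). The same value was -0.23 (-0.30 to -0.14) in pair 3 and -0.44 (-0.55 to -0.32) in pair 2. Over these genes the fall in pair 1 was smaller than in pair 2 and not apart from that in pair 3. The intervals resample genes, which are not independent replicates, and hold no spread between tumours. Genes were picked by their own lowest probe set, so noise in a pair pulls this median toward no change. Pair 1 had 556 genes with such a lowered probe set, against 52 in pair 2 and 89 in pair 3. Signal loss therefore stays open, together with a different response of that tumour.

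The third pattern is the higher globin and ALAS2 signal. Looked at after their values were seen, 6 probe sets that list both alpha globin genes were higher by log2 2.01 to 2.62 over all arrays and 2.64 to 3.18 without pair 1, and higher in all 3 pairs. Of the embryonic globin gene HBE1, 1 probe set was higher (log2 2.74, SE 0.51) and the other was not (0.035, SE 0.12), while HBQ1 (log2 0.26, SE 0.14) and HBZ (0.15, SE 0.14) were higher in 2 of 3 pairs. More host blood in treated tumours could give this, while the red cell markers other than HBB and ALAS2 had a median of 0.13, and these 3 genes do not decide. Their deviations from the group means correlated at 0.69 on average. A smaller share of tumour RNA would raise every host marker, and the 61 members of 4 host tissue lists had a median of 0.023. The deviations of these 61 correlated at only 0.069 on average. They come from different cell types that need not vary together, so this does not show whether the array reads them in mouse RNA. A smaller tumour share therefore stays open, as does globin transcription in the tumour cells themselves, which was not tested.

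The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probe sets, 0 genes and 12 lists, and the highest of the other splits gave 4, 1 and 7. With 0 calls in the real split, 10 of the 10 splits give as many probe sets or genes by construction, which tests nothing, and 1, the real one, gave as many lists. The split with 4 probe sets put both tumours of pair 1 together with untreated tumour 3. Among the 4 splits that part all 3 pairs, the real one had 1424 probe sets at an unadjusted p under 0.05 with the block and the others 545, 503 and 953.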
